A study of Mus musculus with 18 samples.

How the data were processed

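Cortex RNA from 12 mice, 18 libraries in all, was sequenced after poly(A) enrichment with a stranded library kit and paired reads on an Illumina NovaSeq instrument. Per the labels, the authors computed expression with StringTie against the mouse genome build GRCm38. No version and no further step is given, and neither is the time of tissue collection or the hemisphere taken from sham mice. The deposited tables list, for each of 6 pairs of groups, the protein-coding genes whose mean reached 0.5 FPKM in at least 1 of the groups, with the deposited FPKM of each library. They also hold the authors' log2 fold change, the authors' fold change as a ratio, and the authors' p_value and q_value columns. The 2 columns of group levels carry an FPKM heading but were checked to hold the deposited mean log2(FPKM + 1). In each of the 6 files, 100.0% of the authors' p values equal, within 1e-06, an unpaired equal-variance test on log2(FPKM + 1), and 0.0% equal a paired one. The left hemisphere is the side with spreading depolarization (SD) and the right one the contralateral side, as the group columns of the tables give it. Stimulus and SD go together in every comparison of the SD hemisphere, and side does so between the hemispheres. Their effects cannot be separated. In each file, 1 line held no data and was left out.

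The tables hold no read counts, so the depth of each library is unknown, and neither a counting interval nor a floor is given. The FPKM of the listed genes summed to between 223564 and 237318 per library in the KCl system and to between 217205 and 225813 in the optogenetic system. Between 11668 and 12030 genes per library reached 1 FPKM.

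Each system was tested with its 9 libraries together. Genes with a mean of at least 0.5 FPKM over those libraries were kept, and log2(FPKM + 0.5) was fitted with limma 3.58.1 in R 4.3.3, with 3 groups and a prior variance that follows the mean. A gene was called at a Benjamini-Hochberg (BH) adjusted p under 0.05. Fold changes are on the log2(FPKM + 0.5) scale, which understates the change of genes with low values. Errors of fold changes are standard errors (SE) from limma, errors of FPKM are standard deviations. The difference between the KCl and the optogenetic effect was tested as an interaction in a limma fit of all 18 libraries. For 34 gene lists fixed before the data were examined, limma's camera compared the members with all other genes at a preset inter-gene correlation of 0.01. Its p was BH adjusted over the lists of a comparison, and the test was repeated with an estimated correlation. A list needed 5 measured members, which left 33 to test. Members were also counted after BH adjustment over the list alone.

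Genes are named by a rule set before the data were examined. For SD against sham these are the called genes with non-overlapping groups and an established symbol, up to the 10 largest rises and the 6 largest falls, up to 3 called members of each list, and a few genes chosen in advance. For the other comparisons the rule takes the 5 largest rises and the 3 largest falls, or the 3 smallest p where none was called.

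Left and right libraries of a number are by their titles the sides of 1 mouse, and sham mice share only the number. In comparisons with sham a block for the replicate number therefore does not stand for the mouse. Mice are the replicates, 3 per group. The main fit of each system does not use the pairing of sides and treats its 9 libraries as independent. The alternatives tried were other pseudocounts (0.1 and 1), other filters, median-of-ratios and quantile scaling, a constant prior variance, blocks for the replicate or the mouse, fits of 6 libraries, an added fold threshold, the authors' own p and q columns, and leaving out each library. A fit was tested on simulated data with known changes: for KCl SD against sham, limma recovered 64.6% of 1.5-fold, 92.3% of 2-fold and 98.4% of 4-fold changes, and 6 of 170 calls were false. For the optogenetic system the shares were 77.3%, 92.3% and 96.9%, with 11 of 185 calls false. The real comparisons gave 9 and 62 calls, so the adjusted threshold of the simulations was looser. Simulated noise was also independent between genes, with variances drawn from the fitted prior. The shares recovered therefore do not carry over to the real comparisons. Transcript lengths came from the GENCODE M21 annotation. Tables were read with Python 3.11.15 and pandas 2.3.3.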

Results

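The study measured gene expression in the cortex of healthy female mice, 7 to 8 weeks old, after spreading depolarization, a slow wave of near-complete depolarization of neurons and glia that underlies the migraine aura. Each stimulated mouse had 4 such waves in 2 h at 30 min intervals, seen by intrinsic optical signal imaging. In the KCl system the waves were set off by focal KCl in C57BL/6 mice, and sham mice received NaCl. In the optogenetic system they were set off by light (2 mW for 20 s) in mice heterozygous for Thy1-ChR2-YFP, a light-gated channel expressed in neurons, with sham mice of their own. Each system has 3 libraries of the SD hemisphere, 3 of the contralateral hemisphere of the same mice and 3 of sham mice. The deposited tables list 13287 genes in the KCl system and 13221 in the optogenetic system, 13029 of them in both. Across genes, log2(FPKM + 1) of any pair of libraries correlated at 0.9786 to 0.9885 in the KCl system and at 0.9780 to 0.9887 in the optogenetic system.

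The first question was what SD set off by KCl changes in the cortex relative to NaCl sham. Genes induced by neuronal activity were higher in the SD hemisphere. Ptgs2 (ENSMUSG00000032487.8, chromosome 1, 150100031 to 150108227), which encodes the inducible cyclooxygenase of prostaglandin synthesis, rose from 7.98 ± 4.00 to 61.2 ± 16.3 FPKM (standard deviation, n = 3 mice each), a log2 fold change of 2.96 (SE 0.37, adjusted p = 0.0287). Fosb, a subunit of the AP-1 transcription factor, rose by 2.38 (SE 0.24) and Dusp5, a nuclear phosphatase of ERK, by 1.62 (SE 0.18). The small GTPase Arl4d rose by 1.56, the transcriptional coregulator Cited2 by 1.29, the clock gene Per1 by 0.71 and Ifrd1 by 0.67. The genes that fell were Phc3, of a Polycomb complex, by 1.78 (SE 0.13), and Ppp6c, the catalytic subunit of protein phosphatase 6, by 0.44 (SE 0.05).

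Immediate early genes, the first genes transcribed after neuronal activity, led the gene groups in the KCl system. Of 34 measured, 26 rose and Klf2 fell when adjusted over the list alone, and 3 rose over all genes tested. Npas4, a transcription factor that depends on neuronal activity, was at 192 ± 25.2 FPKM in the SD hemisphere and at 26.9 ± 24.8 in sham (standard deviation, n = 3), with sham libraries at 27.5, 1.82 and 51.4 FPKM. Its log2 fold change of 3.68 (SE 0.92) did not pass over all genes (adjusted p = 0.357), and neither did that of Fos, 2.78 (SE 0.38, adjusted p = 0.0558). Fos passed without NaCl sham replicate 1 or 2 and with the filter at a mean of 2 FPKM, and its adjusted p ranged from 0.0199 to 0.169 over the alternatives. Among 16 phosphatases and feedback regulators of MAP kinase signalling, 9 rose when adjusted over the list alone, with Dusp6 at 1.94 and Rgs2 at 1.61, and 1 rose over all genes. Both lists were called higher by camera, with adjusted p of 6.55e-40 and 5.55e-14, and adjusted p = 0.0496 for each with an estimated correlation.

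Smaller groups moved as well in KCl SD against sham, and none of those calls held with an estimated correlation. Among 24 neurotrophic and secreted factors, Vgf, Nptx2, Bdnf and Scg2 rose when adjusted over the list alone and 0 over all genes (camera adjusted p = 0.00905). The call was lost at adjusted p = 0.193 with an estimated correlation and at 0.0903 without NaCl sham replicate 2. Bdnf, a neurotrophin, had a log2 fold change of 0.76 (SE 0.17, adjusted p = 0.285 over all genes). Plaur, Thbs1 and Adamts1, of 16 matrix remodelling and angiogenesis genes, rose when adjusted over the list alone (adjusted p = 0.189 with an estimated correlation). Endothelial, interferon-stimulated and meningeal lists were called lower, with medians of -0.17, -0.15 and -0.31 (adjusted p = 0.193, 0.193 and 0.581 with an estimated correlation). All 3 calls ended without NaCl sham replicate 1, at adjusted p of 0.111, 0.0976 and 0.12. Among the meningeal genes Col1a1, Lum and Col1a2 fell and Igf2 rose when adjusted over the list alone. Choroid plexus genes, which mark ventricular tissue, were called higher with a median of 0.56 (adjusted p = 0.71 with an estimated correlation), 0 of 10 members passing. Ttr of that list ranged from 10.3 to 817 FPKM among the sham libraries. That call ended without KCl SD replicate 2 (adjusted p = 0.0522) and with median-of-ratios scaling (0.055), and the direction turned without NaCl sham replicate 3 (adjusted p = 0.886). The circadian list (Errfi1, Ciart, Per1 and Sgk1 higher when adjusted over the list alone) and the heat shock list were called higher, the pericyte list lower and the list of striatal, hippocampal and thalamic markers higher. These lists completed the 12 called, with adjusted p = 0.443, 0.229, 0.459 and 0.724 with an estimated correlation. The circadian call ended without NaCl sham replicate 1 (adjusted p = 0.283), and the heat shock one without KCl SD replicate 1 (0.0525) or NaCl sham replicate 1 (0.0615) or 2 (0.0582). The pericyte call ended without KCl SD replicate 1 (0.1) or 3 (0.0764) or NaCl sham replicate 1 (0.211). The striatal one ended without KCl SD replicate 1 (0.435) or 2 (0.0837) or NaCl sham replicate 2 (0.198) or 3 (0.421), and with median-of-ratios scaling (0.14).

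The glial and inflammatory genes and lists named next were not called in KCl SD against sham over all genes. Gfap, the intermediate filament of astrocytes, had a log2 fold change of -0.20 (SE 0.18, adjusted p = 0.827), positive (0.02) without KCl SD replicate 3, and Hmgb1, a nuclear protein released from injured cells, one of -0.04 (SE 0.05, adjusted p = 0.915). None of the lists of reactive astrocytes, microglia, activated microglia, inflammasome and cytokines was called by camera, with adjusted p from 0.34 to 0.916. Ccl7 and Nfkbiz of the 15 cytokine and NF-kappaB genes rose when adjusted over the list alone, and 0 over all genes. Il1b and Calca were not analysed here.

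In total limma called 9 of 12972 genes in KCl SD against sham, 7 higher and 2 lower. An unadjusted p under 0.05 was found for 1028 genes, 316 higher and 712 lower. The median log2 fold change over all genes was -0.027, and -0.000 with median-of-ratios scaling, so a small shift of all values goes with the excess of lower genes. The count of called genes was 1 without KCl contralateral replicate 1, 4 without KCl contralateral replicate 2 or 3, and 1 with a constant prior variance. With the replicate number as a block Per1, Ifrd1 and Ppp6c lost their calls. The count was 3, 14 and 17 without KCl SD replicate 1, 2 and 3, and 22 without NaCl sham replicate 1. Phc3 kept its call without each of the 9 libraries. The other 8 genes lost theirs without KCl contralateral replicate 1 (adjusted p 0.0521 to 0.0584), 6 of them without KCl contralateral replicate 2 or 3 (0.0505 to 0.0611) and 7 without KCl SD replicate 1 (0.0584 to 0.126). Without KCl SD replicate 2 it was Arl4d and Ppp6c, without replicate 3 Ptgs2, Ifrd1 and Ppp6c (0.0563 to 0.0794). Without NaCl sham replicate 1 it was Ifrd1 and Ppp6c (0.0548), and without 2 or 3 it was 4 or 5 genes (0.0505 to 0.105). Phc3 is among the genes whose libraries lie on 2 separate levels. It was at 3.51 to 5.11 FPKM in NaCl sham and at 0.898 to 0.985 in the SD hemisphere. In the optogenetic SD group it was at 4.11 in replicate 3 and at 1.03 and 1.14 in the others.

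**Figure D1:**
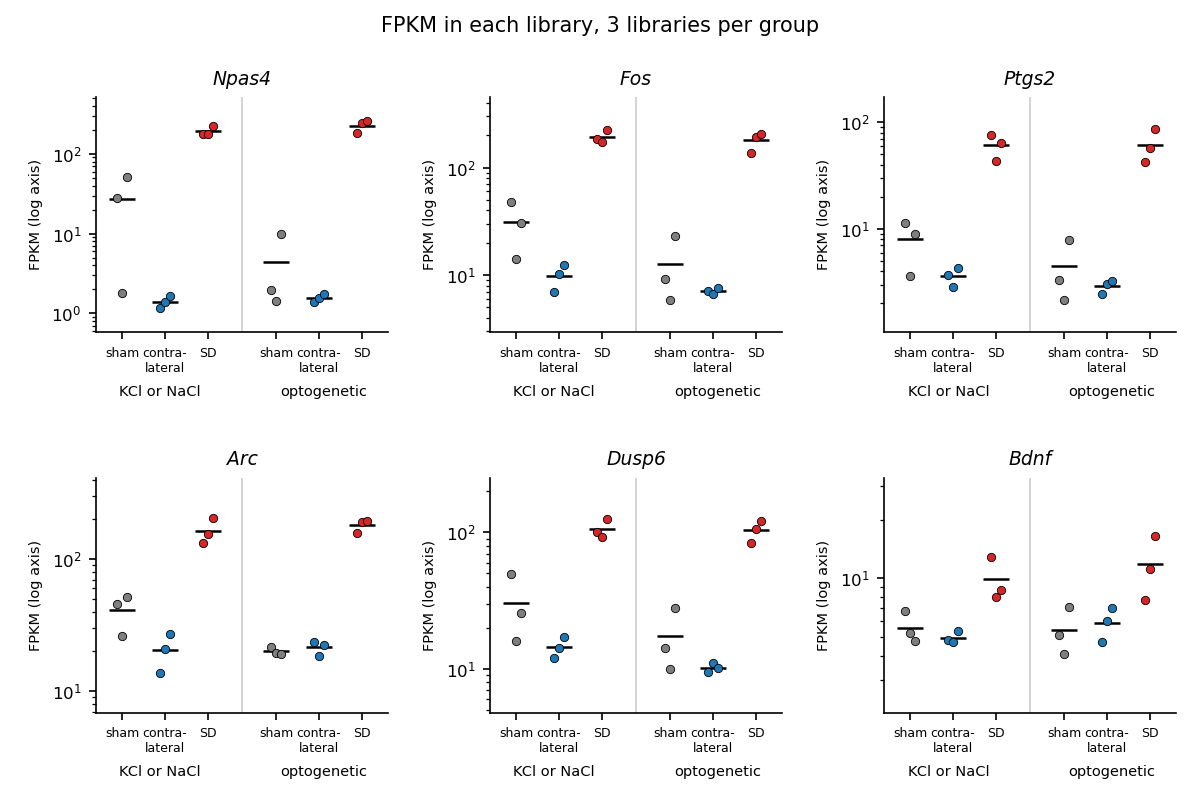
FPKM (log axis) of Npas4, Fos, Ptgs2, Arc, Dusp6 and Bdnf in each of the 18 libraries, by group and system; points are libraries and bars are group means. The SD libraries of Npas4 lie at 177 to 256 FPKM and the contralateral ones at 1.17 to 1.75, while the NaCl sham libraries spread from 1.82 to 51.4.

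The SD hemisphere was next compared with the other side of the same mice after KCl. Npas4 (ENSMUSG00000045903.8, chromosome 19, 4984355 to 4989971) was at 192 ± 25.2 FPKM in the SD hemisphere and at 1.40 ± 0.233 in the contralateral one (standard deviation, n = 3), a log2 fold change of 6.66 (SE 0.92, adjusted p = 0.0185). Fos rose by 4.25 (SE 0.38), Ptgs2 by 3.88 (SE 0.37), the matrix protein gene Cyr61 by 3.63 (SE 0.40) and Fosb by 3.21 (SE 0.24). The largest falls were those of Timm22, part of a translocase of the mitochondrial inner membrane, by 1.06 (SE 0.15), of the zinc finger gene Rbak by 0.59 (SE 0.10) and of Dffb, a nuclease active in apoptosis, by 0.57 (SE 0.09). Timm22 also lay on 2 levels, with means of 2.62 and 5.64 FPKM, that cut across groups: it was at 5.09 and 5.62 FPKM in optogenetic sham replicates 1 and 3 and at 2.16 in replicate 2.

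Of the 34 immediate early genes, 26 were higher and Klf2 lower on the SD side when adjusted over the list alone, and 18 were higher over all genes. Of 16 MAP kinase regulators, 11 rose when adjusted over the list alone, Dusp6 by 2.84 and Rgs2 by 2.23, and 6 over all genes. Thbs1, Adamts1 and Plaur of the matrix remodelling list rose when adjusted over the list alone, and Thbs1 over all genes. These 3 lists were called higher by camera (adjusted p = 1.49e-40, 1.47e-18 and 2.20e-04), and adjusted p = 0.0449, 0.0366 and 0.0449 with an estimated correlation. Nptx2, Bdnf, Inhba, Adcyap1 and Scg2 of the secreted factors rose when adjusted over the list alone, 1 of them over all genes (adjusted p = 0.0513 with an estimated correlation). Heat shock genes (median 0.08; Dnajb4 and Dnajb1 in the list alone) and choroid plexus genes (median 0.91; 0 members) were also called higher, with adjusted p = 0.223 and 0.736 with an estimated correlation. The first call ended without KCl contralateral replicate 2 (adjusted p = 0.0941) and the second without KCl contralateral replicate 3 (adjusted p = 0.14), in which Ttr was at 12.4 FPKM against 352 and 454 in replicates 2 and 1.

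In total limma called 45 of 12972 genes between the hemispheres after KCl, 41 higher and 4 lower. An unadjusted p under 0.05 was found for 1281, 500 higher and 781 lower. Over all genes the median log2 fold change was -0.023, and -0.000 with median-of-ratios scaling. With the replicate number as a block limma called 32 higher and 1 lower, and the falls of Timm22 (adjusted p = 0.0882), Rbak and Dffb lost their calls. With a block for the mouse on the 6 libraries of the stimulated mice it called 30 higher and 1 lower, and with the mouse as a random block 69 genes, these 3 falls included. Without KCl SD replicate 1 or 3 it was 28 or 29, and without KCl contralateral replicate 2 or 3 it was 18 or 24. Rbak also lost its call with median-of-ratios scaling or quantile normalization. Npas4, Timm22, Rbak and Dffb missed the threshold without any 1 of the 6 libraries compared (adjusted p 0.0627 to 0.226), and Rbak without NaCl sham replicate 1 or 3 and Dffb without 2 or 3 as well (0.0603 to 0.0825).

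Between the contralateral hemisphere and sham, the question was whether the side without SD differs from the cortex of mice that had none. In the KCl system limma called 1 of 12972 genes, with 727 at an unadjusted p under 0.05. Phc3 fell by 1.74 (SE 0.13, adjusted p = 0.00472). It went from 4.54 ± 0.897 to 0.999 ± 0.0610 FPKM (standard deviation, n = 3), on the 2 levels described for it. In the optogenetic system it called 1 of 13001, with 754 at an unadjusted p under 0.05. Mid1 (ENSMUSG00000035299.16, chromosome X, 169685199 to 170005736), a ubiquitin ligase bound to microtubules, fell by 1.44 (SE 0.11, adjusted p = 0.00655), from 5.16 ± 0.766 to 1.57 ± 0.172 FPKM. With the replicate number as a block 0 genes were called by limma in either system. Sham mice share only that number with stimulated mice, so the loss says nothing about effects of the mouse. In the KCl system the count was 0 without contralateral replicate 3 (Phc3 at adjusted p = 0.0506), 7 without contralateral replicate 1, 3 without contralateral replicate 2 and 2 without SD replicate 2. It was 6 without NaCl sham replicate 2 and 4 without NaCl sham replicate 3. In the optogenetic system it was 4 without SD replicate 3 or sham replicate 1 and 5 without contralateral replicate 2.

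Gene groups went mostly lower on the contralateral side than in sham, and no list call held with an estimated correlation in either system. Immediate early genes had a median log2 fold change of -0.24 in the KCl system (camera adjusted p = 2.52e-05) and -0.17 in the optogenetic system (0.0111), with 0 members passing in either. Neither call was kept (adjusted p = 0.469 and 0.818 with an estimated correlation). Npas4 was at 1.40 ± 0.233 FPKM contralaterally and 26.9 ± 24.8 in NaCl sham (log2 fold change -2.99, SE 0.92, adjusted p = 0.877). These calls ended without KCl contralateral replicate 1 (adjusted p = 0.066), and without optogenetic contralateral replicate 1 (0.197) or sham replicate 3 (0.946, median 0.01). MAP kinase regulators were called lower in the KCl system (median -0.33; adjusted p = 0.446 with an estimated correlation). Red blood cell genes were called lower in the optogenetic system, with 5 of 5 members lower when adjusted over the list alone, 0 over all genes and a median of -0.90 (adjusted p = 0.776 with an estimated correlation). Hbb-bs was at 353 FPKM in optogenetic sham replicate 3 and at 147 and 164 in the other sham libraries. The other lists called lower were interferon-stimulated genes in both systems, meningeal and prostaglandin genes in the KCl system, and homeostatic astrocyte, matrix remodelling and microglia genes in the optogenetic system, with adjusted p from 0.446 to 0.818 with an estimated correlation. Respiratory chain genes were called higher in both systems, with a median of 0.05 in each, and heat shock genes in the optogenetic system, with a median of 0.08 (adjusted p from 0.763 to 0.818 with an estimated correlation). In the KCl system single omissions ended the calls of meningeal (contralateral replicate 3, adjusted p = 0.0574; sham replicate 1, 0.211) and prostaglandin genes (contralateral replicate 1, 0.0939, or 3, 0.13; sham replicate 1, 0.409). They also ended those of respiratory chain (contralateral replicate 1, 0.306; sham replicate 2, 0.144, or 3, 0.577) and interferon genes (contralateral replicate 1, 0.179; sham replicate 1, 0.26, or 2, 0.119). In the optogenetic system leaving out sham replicate 3 ended the calls of homeostatic astrocyte (0.21), matrix (0.434), interferon (0.249), microglia (0.157) and respiratory chain genes (0.127). Leaving out contralateral replicate 1 ended those of matrix (0.124), interferon (0.103), microglia (0.0543) and respiratory chain genes (0.61). Microglia genes also lost theirs without contralateral replicate 2 (0.0564) or 3 (0.159) or sham replicate 2 (0.283), and respiratory chain genes without contralateral replicate 2 (0.0872) or sham replicate 1 (0.229). Heat shock genes lost theirs without contralateral replicate 3 (0.37) or sham replicate 1 (0.229) or 2 (0.188).

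Optogenetic SD was compared with its own sham to see the response without applied potassium. The labels give light for the stimulated mice alone, so responses to the light itself and to SD cannot be told apart. Npas4 rose from 4.44 ± 4.74 to 226 ± 39.7 FPKM (standard deviation, n = 3 mice each), a log2 fold change of 5.93 (SE 0.52, adjusted p = 0.00167). Fos (ENSMUSG00000021250.13, chromosome 12, 85473890 to 85477273) rose from 12.7 ± 9.14 to 179 ± 36.9 FPKM, a change of 3.96 (SE 0.40). Ptgs2 rose by 3.76 (SE 0.39), Fosb by 3.20 (SE 0.51) and Cyr61 by 3.01 (SE 0.26). Arc (ENSMUSG00000022602.14, chromosome 15, 74669083 to 74672570), which acts at activated synapses, rose by 3.14 (SE 0.10, adjusted p = 3.94e-06). Dusp6, Nr4a1, Egr2 and Junb rose by 2.51 to 2.65. Of the called genes fewer fell than rose. Among the falls were Mid1 by 1.46 (SE 0.11), the Notch target Hes1 by 1.11 (SE 0.15) and the Polycomb gene Cbx2 by 1.02 (SE 0.14). Ucma fell by 0.90, the zinc finger gene Insm1 by 0.70 and Stim1, a calcium sensor of the endoplasmic reticulum, by 0.63. Cbx2, Ucma and Insm1 lie near the 0.5 FPKM filter. Split into lower and upper libraries, their means were 0.375 and 1.32, 0.328 and 0.943, and 0.641 and 1.29 FPKM. Over the alternatives their log2 fold changes ranged from -1.49 to -0.74, -1.46 to -0.62 and -0.98 to -0.52.

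By group, 28 of 34 immediate early genes rose and Klf2 fell when adjusted over the list alone, and 19 rose over all genes. Of 16 MAP kinase regulators 11 rose when adjusted over the list alone and 9 over all genes, Dusp5 by 2.23 and Rgs2 by 1.73. Camera called both lists higher (adjusted p = 9.62e-53 and 6.82e-20), and neither held (adjusted p = 0.0678 for each with an estimated correlation). The same held for other groups of higher genes, and of the 10 lists called 1, higher, is not described here. Nptx2, a pentraxin secreted at excitatory synapses, rose by 1.80 (SE 0.30), and Bdnf, Scg2 and Nrn1 of the secreted factors rose when adjusted over the list alone (adjusted p = 0.303 with an estimated correlation). The heat shock cochaperones Dnajb5 and Dnajb1 rose by 0.57 and 0.51, and Dnajb4 in the list alone (adjusted p = 0.315 with an estimated correlation). Ctgf rose by 0.59 among 22 cortical layer markers (list median 0.07, adjusted p = 0.315 with an estimated correlation), and that call ended without SD replicate 2 (0.0666) or sham replicate 3 (0.179).

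Groups called lower after optogenetic SD were glial, interferon and blood genes, and none held with an estimated correlation. Gja1, the connexin 43 of astrocytes, fell by 0.50 (SE 0.08, adjusted p = 0.0319), and Gjb6 of the 16 homeostatic astrocyte genes in the list alone (adjusted p = 0.528 with an estimated correlation). All 5 of 5 red blood cell genes fell when adjusted over the list alone and 0 over all genes (median -1.09; adjusted p = 0.315 with an estimated correlation), and Hbb-bs was at 353 FPKM in sham replicate 3 and at 68.5 to 164 in the other SD and sham libraries. Interferon-stimulated genes (median -0.19) and oligodendrocyte genes (median -0.17) were called lower with 0 members passing, adjusted p = 0.315 and 0.838 with an estimated correlation. The interferon call ended without SD replicate 1 (adjusted p = 0.074) or sham replicate 3 (0.0733), and the astrocyte call without SD replicate 2 (0.0666) or sham replicate 3 (0.291). The oligodendrocyte call ended without SD replicate 2 (0.146) or 3 (0.209) or sham replicate 2 (0.558).

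Single members of other lists changed as well after optogenetic SD. Nfkbiz, a regulator of NF-kappaB, rose by 0.93 (SE 0.09) and the potassium channel gene Kcnj2 by 1.29 (SE 0.14). In the circadian list Per1 rose by 0.95, Errfi1, a feedback inhibitor of the EGF receptor, by 0.85 and Cry2 by 0.31. The cytokine, potassium channel and circadian lists were not called (camera adjusted p from 0.108 to 0.847). Per1 also belongs to the immediate early list and Errfi1 to the MAP kinase list, which were called higher. Bdnf had a log2 fold change of 1.02 (SE 0.27, adjusted p = 0.312), Gfap one of -0.02 (SE 0.13, adjusted p = 0.975) and Hmgb1 one of 0.08 (SE 0.11, adjusted p = 0.884). That of Gfap ranged from -0.12 to 0.10 over the alternatives and changed sign without SD replicate 1 or sham replicate 3.

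In total limma called 62 of 13001 genes in optogenetic SD against sham, 53 higher and 9 lower. An unadjusted p under 0.05 was found for 1135, 483 higher and 652 lower. Over all genes the median log2 fold change was -0.017, and -0.005 with median-of-ratios scaling. The count of called genes was 38 without SD replicate 3 and 39 without sham replicate 2. Npas4, Fos, Ptgs2, Arc, Cyr61, Dusp6, Nr4a1, Egr2, Junb, Mid1, Ucma, Stim1, Dusp5, Nfkbiz, Dnajb5, Dnajb1 and Kcnj2 kept their calls without each of the 9 libraries. The other 11 genes named here, Fosb, Hes1, Cbx2, Insm1, Nptx2, Rgs2, Gja1, Ctgf, Per1, Errfi1 and Cry2, all lost theirs without sham replicate 2 (adjusted p 0.057 to 0.154). Of these, 9 lost it without sham replicate 1 and 10 without SD replicate 3 (0.0519 to 0.212), 8 and 7 without SD replicates 1 and 2 (0.0514 to 0.178) and 7 without contralateral replicate 2 (0.057 to 0.0851). It was 4 without contralateral replicate 1 or 3 or sham replicate 3 (0.0505 to 0.146). With a constant prior variance Fosb, Nptx2, Gja1, Ctgf and Cry2 lost theirs, with quantile normalization Insm1 and Nptx2, and with the replicate number as a block Gja1, Ctgf and Cry2. Ctgf lost it with the mouse as a random block as well. Mid1 was at 4.32 to 5.82 FPKM in the optogenetic sham libraries and at 0.586 to 1.69 in the other 15, NaCl sham included. Stim1 was at 4.65 FPKM in the SD libraries and 7.44 in sham. A split into 2 levels explained 0.794 of its variance and cut 2 groups, under the share of 0.9 required of genes on 2 levels.

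**Figure D2:**
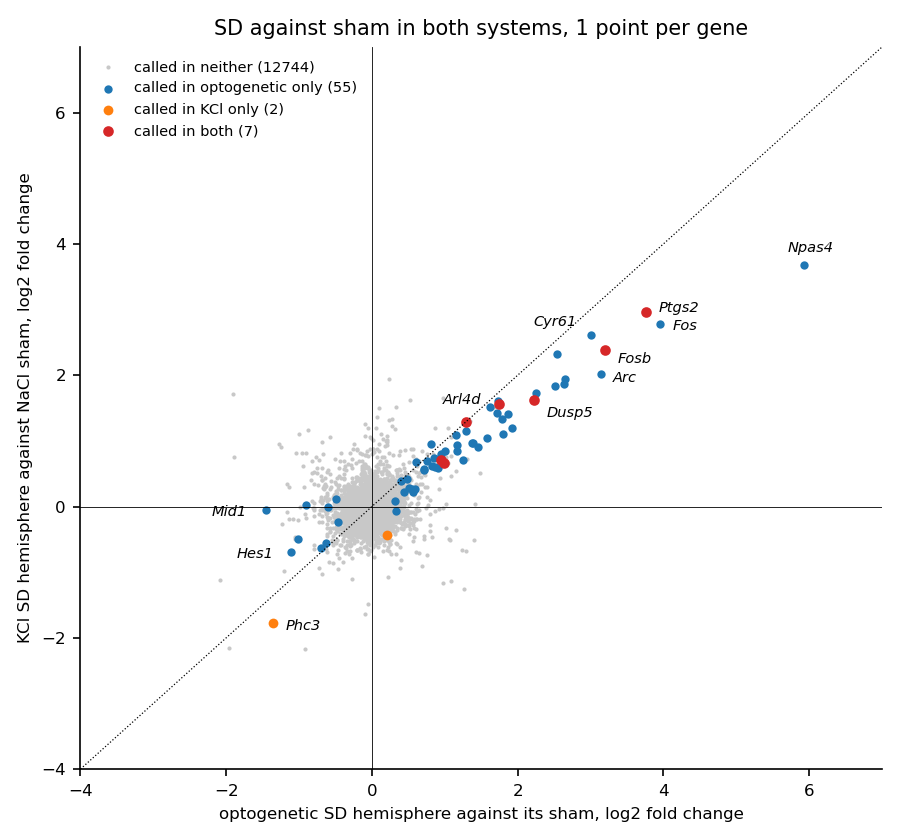
Log2 fold change of SD against sham in the KCl system (vertical axis) and in the optogenetic system (horizontal axis), 1 point for each of 12808 genes, coloured by where limma called the gene; the dotted line marks equal values. The 7 genes called in both lie in the upper right, and Npas4 lies at 5.93 and 3.68.

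Between the hemispheres of the optogenetic mice, Npas4 rose by 6.76 (SE 0.52, adjusted p = 6.45e-04), from 1.56 ± 0.185 to 226 ± 39.7 FPKM (standard deviation, n = 3). Fos rose by 4.53 (SE 0.40), Ptgs2 by 4.14 (SE 0.39), Fosb by 3.71 (SE 0.51) and Cyr61 by 3.42 (SE 0.26). The largest falls were those of Pcdh7, a protocadherin, by 1.26 (SE 0.21), Cbx2 by 1.19 (SE 0.14) and Hes1 by 1.11 (SE 0.15), and Hes1 was at 3.77 ± 0.966 against 8.62 ± 1.15 FPKM. Pcdh7 came close to the genes on 2 levels: levels with means of 9.7 and 23.6 FPKM cut 3 groups. They explained 0.875 of its variance, under the 0.9 required. Its optogenetic sham libraries were at 7.85 to 10.2 FPKM, close to the SD ones at 5.82 to 11.2.

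Of 34 immediate early genes 30 rose when adjusted over the list alone and 21 over all genes, and of the MAP kinase regulators 11 and 8. These lists were called higher by camera (adjusted p = 2.25e-61 and 1.61e-22), with adjusted p = 0.0498 for each with an estimated correlation. Matrix remodelling genes were called higher with a median of 0.28 and 0 members passing (adjusted p = 0.241 with an estimated correlation). Of the 8 lists called 1, higher, is not described here. Further calls were secreted factors (Nptx2), circadian and heat shock genes higher and respiratory chain genes lower, with adjusted p = 0.744, 0.241, 0.833 and 0.833 with an estimated correlation. Each of those 4 calls ended with median-of-ratios scaling (adjusted p 0.0518, 0.0703, 0.0567 and 0.111), while the list of striatal, hippocampal and thalamic markers became called lower. The secreted factors lost the call without SD replicate 2 (0.116) or 3 (0.0614) or contralateral replicate 1 (0.312), and circadian genes without SD replicate 1 (0.134), contralateral replicate 3 (0.231) or sham replicate 3 (0.0559). Heat shock genes lost it without SD replicate 2 (0.249) or 3 (0.193), contralateral replicate 1 (0.55) or sham replicate 2 (0.0571) or 3 (0.0559). Respiratory chain genes lost it without SD replicate 1 (0.0736) or 3 (0.193), contralateral replicate 1 (0.604) or 2 (0.0914) or sham replicate 2 (0.0571) or 3 (0.0559).

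In total limma called 69 of 13001 genes between the hemispheres of the optogenetic mice, 62 higher and 7 lower. An unadjusted p under 0.05 was found for 1134, 429 higher and 705 lower. Over all genes the median log2 fold change was -0.023, and -0.000 with median-of-ratios scaling. With the replicate number as a block 66 genes were called. With a block for the mouse on the 6 libraries of the stimulated mice it was 49, and with the mouse as a random block 132. Npas4, Fos, Ptgs2, Cyr61 and Cbx2 kept their calls without each of the 9 libraries. Fosb lost its call without SD replicate 2 or 3 or any contralateral library, Hes1 without SD replicate 1 or 3 or contralateral replicate 1 or 2, and Pcdh7 without any library other than SD replicates 1 and 3 (adjusted p 0.058 to 0.178). Pcdh7 also lost its call with quantile normalization or a constant prior variance.

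**Figure D3:**
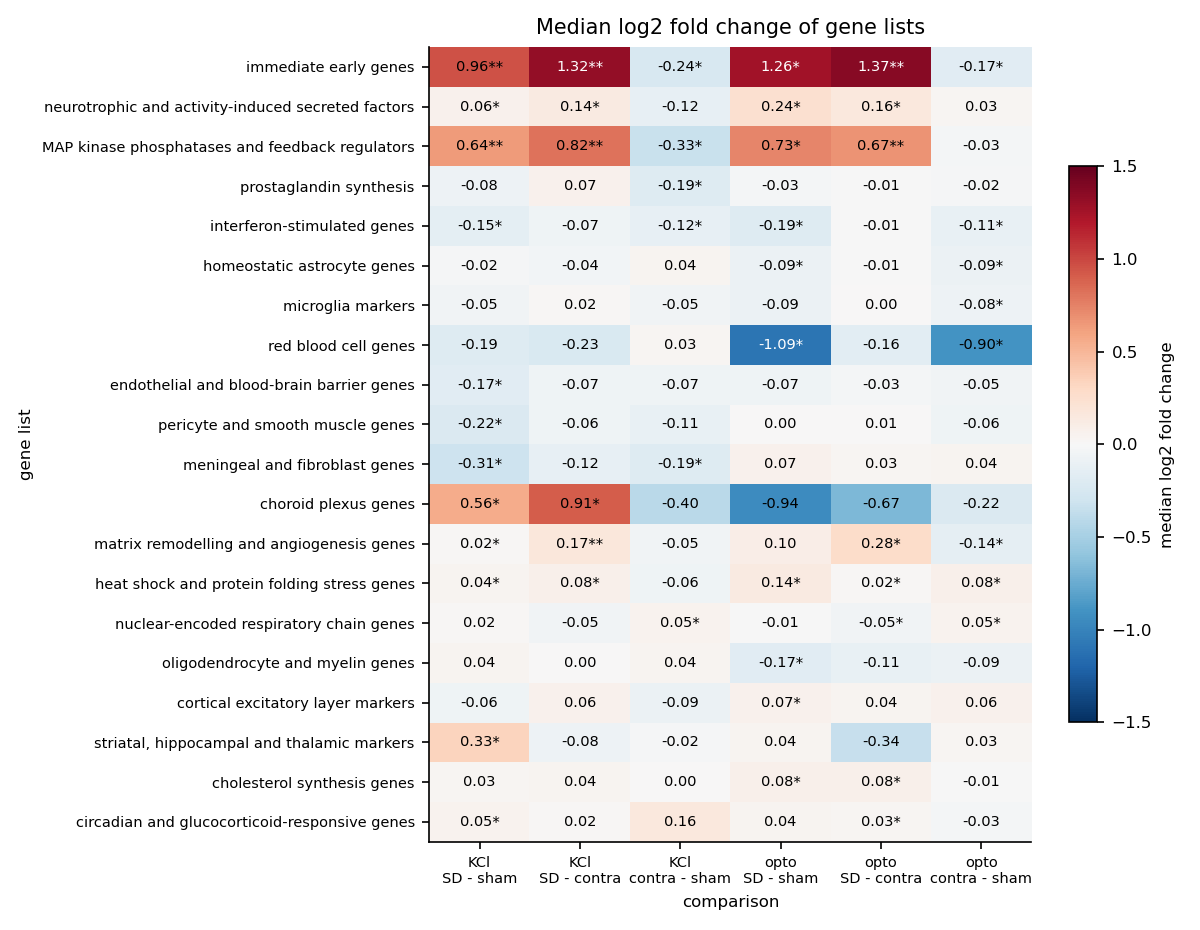
Median log2 fold change of the gene lists (rows) that camera called in at least 1 of the 6 comparisons (columns), on a colour scale from -1.5 to 1.5. A star marks a camera adjusted p under 0.05 at the preset correlation, and 2 stars mark lists that also pass with an estimated correlation: the immediate early list has medians of 0.96 to 1.37 in the 4 comparisons of the SD hemisphere.

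Across methods, the question was whether SD set off by potassium and by light gives the same response. The method, the mouse genotype, the sham group and the deposited series change together, so the method cannot be separated from the others. Of 12808 genes tested in both systems, 7 rose in SD against sham in both, where independent lists would share 0.029. They were Arl4d, Cited2, Dusp5, Fosb, Ifrd1, Per1 and Ptgs2. Between the hemispheres 35 genes rose in both, where independent lists would share 0.198, among them Npas4, Fos, Arc, Egr1, Nr4a1 and Kcnj2. No called fall was shared. In SD against sham 2 genes fell after KCl and 9 after light, with 0 in both, and between the hemispheres 4 and 7, with 0 in both. Of the 62 genes called in optogenetic SD against sham, 58 had the same sign after KCl, and 8 of the 9 KCl calls had the same sign after light, Ppp6c being the exception. Over all genes 54.7% had the same sign, and the log2 fold changes of SD against sham correlated at a Pearson r of 0.34 and a Spearman rho of 0.13 across genes, which are not independent replicates. It was 0.21 without NaCl sham replicate 2.

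No gene passed the limma test of the difference between the systems. For SD against sham 0 of 12930 genes were called, with 715 at an unadjusted p under 0.05, and for SD against contralateral 0, with 794. The smallest p for the first were those of Mid1, with a difference (KCl minus optogenetic) of 1.41 (SE 0.20, adjusted p = 0.0655), Chp1 of -0.40 (SE 0.07, adjusted p = 0.321) and Zfp27 of -0.80 (SE 0.17, adjusted p = 0.822). For the second they were those of Tusc1 (-0.66), Ano3 (0.60) and Camk2n2 (-0.38), each at adjusted p = 0.651. The 95% interval of the difference in SD against sham ran from -2.45 to 0.09 for Fos and from -2.05 to 0.44 for Ptgs2, so log2 differences of up to those sizes were not excluded. For the first test 2 genes were called without KCl SD replicate 3, and 1 without KCl contralateral replicate 2 or 3, NaCl sham replicate 3 or optogenetic sham replicate 1 or 2. For the second it was 27 without KCl contralateral replicate 1 and 1 without KCl SD replicate 3.

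**Figure D4:**
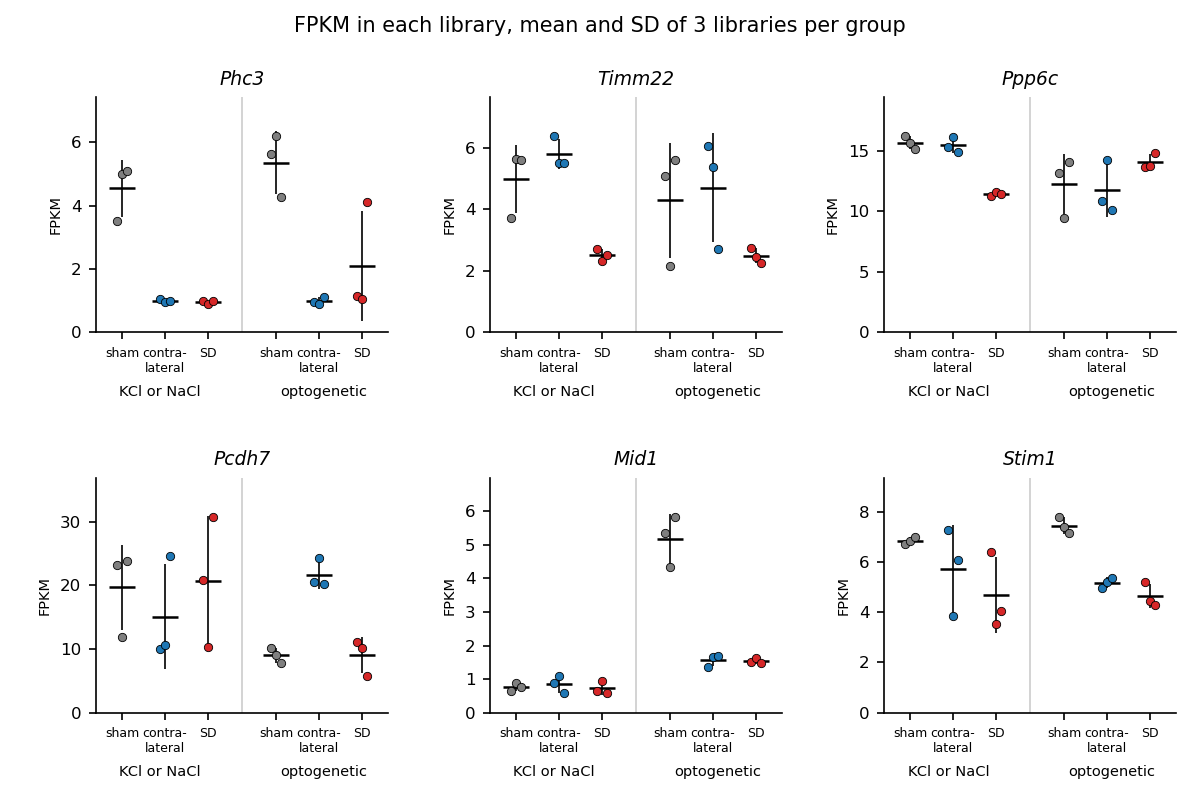
FPKM of Phc3, Timm22, Ppp6c, Pcdh7, Mid1 and Stim1 in each library, by group and system; points are libraries, horizontal bars means and vertical bars standard deviations (n = 3). Phc3 lies at 3.51 to 6.19 FPKM in the 6 sham libraries and in optogenetic SD replicate 3 at 4.11, and at 0.898 to 1.14 in the other 11.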

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

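The tests on the share of left and right sides on different levels, on an exchange of labels, on a mouse without the transgene and on the contralateral immediate early genes were chosen after the result was seen. The fit of averaged effects, its mouse blocks and the splits by mouse were added after seeing the data.

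In the gene list tests the effect in the KCl system differed from that in the optogenetic system in SD against sham for 7 lists. This was a camera test of the difference itself, and none passed with an estimated correlation (adjusted p from 0.652 to 0.663). Method, genotype and sham group change together between the systems, so these differences cannot be assigned to the method. Immediate early genes differed (KCl minus optogenetic) by a median of -0.30 (adjusted p = 0.00107; 0.0923 without NaCl sham replicate 1 and 0.134 without optogenetic sham replicate 2). Red blood cell genes differed by 0.90 (0.00107) and homeostatic astrocyte genes by 0.09 (0.00128), Gja1 alone passing when adjusted over the list alone. Oligodendrocyte genes differed by 0.21 (0.00107; 0.0984 without optogenetic sham replicate 2), and meningeal genes by -0.41 (0.00315; 0.109 without NaCl sham replicate 1 and 0.245 without optogenetic sham replicate 2). Choroid plexus genes differed by 1.47 (0.0016; 0.132 without NaCl sham replicate 3 and 0.13 without optogenetic sham replicate 3). Striatal, hippocampal and thalamic markers differed by 0.63 (0.00579; 0.0881 without KCl SD replicate 1 and 0.132 without NaCl sham replicate 3). In SD against contralateral the choroid plexus genes alone differed, by 1.60 (adjusted p = 0.00517; adjusted p = 0.97 with an estimated correlation). That call ended without KCl SD replicate 2 (0.0549), KCl contralateral replicate 3 (0.0868), optogenetic SD replicate 3 (0.105) or optogenetic contralateral replicate 1 (0.0819).

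The first pattern weighed is a set of 219 of 12930 genes whose libraries fall on 2 separate levels that cut across groups. In a comparison 6 of them were called (Timm22, Trib1, Adrb1, Phc3, Otud1 and Npas4). For these 219 genes 2 levels, with at least 3 libraries on each, explained a share of at least 0.9 of the variance. An inherited variant would put both sides of a mouse on 1 level. The sides were on different levels in 40.8% of 1314 mouse and gene pairs, against 41.1% for unrelated sides. This argues against it for the set as a whole, though not for each gene. Thy1 is also in the set, and both sides of each stimulated mouse were on the same level. For the set as a whole, reads assigned to transcripts of different length when the authors computed FPKM remain a candidate explanation. The ratio of longest to shortest transcript had a median of 4.22 in these genes and 1.99 in random lists of matched expression (percentile 100 of 10000 lists). No other biological explanation was tested, and Npas4 is on its upper level in the 6 SD libraries and 2 NaCl sham libraries. Trib1, Adrb1 and Otud1 each have 7 libraries on the upper level. They rose in optogenetic SD against sham by 1.78, 1.45 and 0.83.

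The second pattern is Thy1 in the library labelled optogenetic sham replicate 2, at 163.2 FPKM, where the KCl series lay at 149.2 to 167.4 and the other 8 optogenetic libraries at 373.9 to 645.3. An exchange of labels with the KCl series would leave a library of that series at the higher level, and 0 lay there. A library made with the KCl series is argued against as well, since 5.4% of 1287 genes separating the series put this library on the KCl side, within the 3.2 to 10.9% of the other optogenetic libraries. A mouse without the Thy1-ChR2-YFP transgene stays open, because no sequence of the transgene is in the tables and Thy1 at 163.2 FPKM is the only value that bears on it. Without this library limma called 39 instead of 62 genes in optogenetic SD against sham. It called 38 without optogenetic SD replicate 3, so the drop is not particular to this library.

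The third pattern is the lower level of immediate early genes in the contralateral hemisphere than in sham. In the KCl system the list stayed called lower without each of the 3 sham libraries, which argues against 1 sham library setting its direction. The call ended without KCl contralateral replicate 1 (adjusted p = 0.066). It was stronger without NaCl sham replicate 2 (median -0.41, camera adjusted p = 2.76e-09), the sham library with the lowest Npas4. Leaving out 1 library at a time cannot tell whether several raised sham libraries together set the direction. In the optogenetic system it stayed called without 2 of 3 and ended without sham replicate 3 (adjusted p = 0.946, median 0.01) or contralateral replicate 1 (0.197), so there 1 sham library may set it. A spread of the whole list between libraries stays open for both, since the lower of the 2 adjusted p with an estimated correlation was 0.469. An effect of SD on the other hemisphere and a rise in some sham mice both stay open, untested beyond these values.

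For comparisons within a system the 6 libraries make 10 splits, too few for a share under 0.05. In SD against sham the real split gave 9 genes after KCl and the highest other 4 (1 of 10 splits as large), and 62 and 7 after light (1 of 10). Between hemispheres it gave 45 against 5 after KCl (1 of 10) and 69 against 4 after light (1 of 10), and among the 4 splits that part all left and right pairs the highest others were 3 and 1. In contralateral against sham it gave 1 against 3 (8 of 10) and 1 against 6 (9 of 10). For lists the real and highest other counts were 12 and 11, 6 and 9, and 6 and 9 in the 3 KCl comparisons (1, 5 and 7 of 10), and 10 and 11, 8 and 9, and 8 and 11 in the optogenetic ones (3, 4 and 6 of 10).

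For the differences and the averaged effects 100 splits were drawn. Chance can be excluded for the count of 125 genes in averaged SD against sham (1 of 100 splits as large, highest other 45), though not for each gene. The same holds for the count of 224 in averaged SD against contralateral (1 of 100, highest other 3). That fit and its splits do not use the pairing of sides within mice. Of the 32 splits that exchange the sides of whole mice, 1 was as large without a block (highest other 1) and 1 of 32 with a mouse block on the 12 libraries (real count 197, highest other 2). Chance cannot be excluded for the 2 genes of averaged contralateral against sham (9 of 100, highest other 3). For both differences the real count is 0, which every split reaches (100 of 100, highest others 4311 and 161), so these splits say nothing about chance. For the count of lists called, chance cannot be excluded for the averaged effects, and for the differences the splits cannot decide. A count of lists does not test any 1 list. The counts were 7 and 1 for the differences (39 and 83 of 100, highest others 16 and 14). They were 11, 6 and 12 for averaged SD against sham, SD against contralateral and contralateral against sham (14, 47 and 9 of 100, highest others 16, 11 and 15). The splits for the differences exchange SD and reference libraries between the KCl and the optogenetic series. Level differences between the series therefore enter those splits, the one with 4311 genes included, and raise their counts of genes and lists.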

How the results depend on the processing

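Of the settings named here, leaving out the genes on 2 levels was chosen after seeing the data. Of the counts and correlations that answer a comparison, 107 stayed the same under the settings that keep all libraries, 18 moved by over 1.5 times, 11 lost and 3 gained their calls. Under the same settings 580 values of the named genes stayed on their side of the threshold, 31 lost and 4 gained a call, and 0 reversed. With 1 library left out 511 stayed, 154 lost and 7 gained a call. Of 56 called pairs of gene and comparison, 29 lost the call in at least 1 setting. With a constant prior variance KCl SD against sham gave 1 gene and optogenetic contralateral against sham 2. With only the 6 libraries of the 2 groups, which leaves fewer samples to estimate the spread, KCl SD against sham gave 4, KCl contralateral against sham 0, optogenetic SD against sham 41 and optogenetic contralateral against sham 4. With the replicate block as a fixed term contralateral against sham gave 0 in both systems, and with the mouse as a random block the hemispheres gave 69 genes after KCl and 132 after light and the difference of SD against sham 1. That difference also gave 1 with a pseudocount of 1 or quantile normalization. Without the genes on 2 levels KCl contralateral against sham gave 0, since Phc3 is among them. By the authors' q the KCl comparisons gave 0, 1 and 0 genes and optogenetic SD against sham and against contralateral 1 and 13. By the authors' p under 0.05 with 1.5-fold, which is not adjusted, the KCl comparisons gave 67, 97 and 20 and optogenetic contralateral against sham 15. With an estimated correlation between genes the called lists went from 12 to 2, 6 to 3 and 6 to 0 in the KCl comparisons, from 10 to 0, 8 to 2 and 8 to 0 in the optogenetic ones, and from 7 and 1 to 0 for the differences. With median-of-ratios scaling the lists of optogenetic SD against contralateral went from 8 to 5, since 4 lost the call and the striatal, hippocampal and thalamic markers gained it, lower. Leaving out each library, the genes of SD against sham, SD against contralateral and contralateral against sham ranged over 1 to 22, 18 to 61 and 0 to 7 after KCl and 38 to 62, 49 to 66 and 1 to 5 after light. The differences ranged over 0 to 2 and 0 to 27, and the correlation between systems over 0.21 to 0.39. The lists ranged over 7 to 13, 6 to 10 and 3 to 10 after KCl, 8 to 15, 5 to 11 and 2 to 13 after light, and 4 to 11 and 0 to 4 for the differences. The choroid plexus list of KCl SD against sham turned from higher to lower without NaCl sham replicate 3 (adjusted p = 0.886), and its adjusted p went down to 3.29e-05 without NaCl sham replicate 2. Where no reason is given above, the cause was not tested. The planned count-based test was not run because the tables hold no counts, and what depth limits could not be computed.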

Other observations

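The fit that averages the effects of both systems, and the genes named from it, were chosen after seeing the data. In averaged SD against sham limma called 125 of 12930 genes, 94 higher and 31 lower. Of these, 66 were called in neither system alone. Bdnf rose by 0.89 (SE 0.17, adjusted p = 0.0175), the stress-induced transcription factor Atf3 by 1.33 (SE 0.21), the AP-1 subunit Fosl2 by 0.93 (SE 0.16), the antiproliferative Tob1 by 0.78 (SE 0.09) and Nfkbid, a regulator of NF-kappaB, by 0.62 (SE 0.10). The arterial connexin Gja4 fell by 0.53 (SE 0.09, adjusted p = 0.00746) and Thap11 by 0.31 (SE 0.04). Immediate early genes and MAP kinase regulators were called higher (adjusted p = 0.00181 for each with an estimated correlation), with 29 and 11 members higher when adjusted over the list alone and 25 and 9 over all genes. Leaving out 1 library gave 95 to 166 genes, and no other setting tried moved this count by over 1.5 times.

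In averaged SD against contralateral limma called 224 genes, 127 higher and 97 lower, 151 of them in neither system alone, and 165 to 262 without 1 library. This fit does not use the pairing of sides within mice. With the mouse as a random block 399 were called (182 higher, 217 lower), the 224 among them. With a fixed mouse block on the 12 libraries of the stimulated mice 197 were called, and of the 127 higher and 97 lower 107 and 42 kept the call. No other setting moved this count by over 1.5 times. Flrt3, an adhesion protein of neurons, rose by 1.12 (SE 0.15), the clock gene Ciart by 0.94 (SE 0.17) and Bdnf by 0.90 (SE 0.17). Hmox1, the inducible heme oxygenase, fell by 0.47 (SE 0.10), the respiratory chain gene Ndufa6 by 0.17 (SE 0.03) and Cox5a by 0.18 (SE 0.04). With the fixed block Flrt3, Ciart, Bdnf, Hmox1 and Ndufa6 kept the call (adjusted p 0.00387, 0.0153, 0.0116, 0.0263 and 0.026) and Cox5a lost it. Matrix remodelling genes were called higher, with 4 members (Adamts1, Adm, Thbs1 and Plaur) when adjusted over the list alone and 3 over all genes (adjusted p = 0.0398 with an estimated correlation). In averaged contralateral against sham 2 genes were called, Phc3 (-1.85, adjusted p = 0.00321) and Mid1 (-0.68, adjusted p = 0.0477). The call of Mid1 rests on the optogenetic system (-1.44), since its KCl value was 0.08. The count of 2 became 1 with a pseudocount of 0.1 or the filter at a mean of 2 FPKM. It was 4 without NaCl sham replicate 2. It was 1 without KCl SD replicate 1 or 3, KCl contralateral replicate 3, NaCl sham replicate 1, any optogenetic SD replicate, optogenetic contralateral replicate 1 or 3 or optogenetic sham replicate 3.

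Some values followed no group. Ttr, a choroid plexus gene, ranged from 2.57 to 1088 FPKM over the 18 libraries and was at 5.07, 465 and 7.06 FPKM in the optogenetic SD libraries. By the authors' q under 0.05 the gene called in KCl SD against contralateral was Npas4, in optogenetic SD against sham Ucma and in optogenetic contralateral against sham Ccl27b, which was higher. Ccl27b is among the genes whose libraries lie on 2 levels that cut across groups (means of 0 and 4.02 FPKM).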
